A study of Homo sapiens with 4 samples.

How the data were processed

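Nuclear RNA of MDA-LM2 cells was measured in 2 libraries with a control siRNA and 2 with an siRNA against METTL3. Per the labels' protocols, cells were transfected with Lipofectamine 2000, nuclear RNA was prepared with a Norgen kit, treated with DNase I and depleted of ribosomal RNA with Ribo-Zero Gold, and libraries were made with ScriptSeq v2 and sequenced on an Illumina instrument. A characteristic of the labels calls the reagent an shRNA, whereas the title and the protocol name siRNA, and siRNA is used here. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 2.1.1, and the same notes name bedtools, Cufflinks and DESeq2 without versions. The deposited files hold 1 integer read count per intron and library, made by the authors with featureCounts. Its version is 1.5.0-p1 per the file headers and 1.6 per the submitters' notes. Read trimming and the settings of the aligner are not given in the sources used here.

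Per the file headers, counting used the options -P, -B, -C and -O with an interval set of introns above an FPKM threshold, without -s, -p or -M. Counts are therefore of reads on either strand, a read in overlapping introns counts for each of them, and reads placed at several sites are not counted. A gene whose introns overlap those of another gene, on either strand, thus shares reads with it, also where this is not repeated below. The interval set is of hg19 RefSeq introns and names a TARBP2 knockdown experiment of nuclear and cytoplasmic RNA, so the introns present were selected elsewhere. It holds 185763 introns of 24188 accessions, with a median length of 1665 nt, and 12126 have no count in any library. Each interval starts 1 base before the intron. Of 152571 gaps between introns that match an annotated exon by accession, 147538 (96.7%) were exactly 1 base shorter than that exon in GENCODE v29. A read of spliced mRNA that covers this base can therefore be counted, and the closing section tests what this does for the G2/M list and for short introns. Intron counts are not measures of mature mRNA, and mitochondrially encoded and small structured RNAs have 0 intervals and are not measured.

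Accessions were named with the RefSeq gene table (23659 accessions) and GENCODE v29 (288 more), and 241 stayed without a name. Counts were summed over introns with the same gene symbol, which gave 18352 genes. The unnamed introns held 0.376%, 0.379%, 0.371% and 0.370% of the counts of siControl 1, siControl 2, siMETTL3 1 and siMETTL3 2. GENCODE v29 is on GRCh38, so it served for names and exon lengths only, and all coordinates are those of the files on hg19. No hg19 sequence was used, so GC content was not examined here.

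Genes were tested with edgeR 4.0.16 (TMM factors 1.02, 0.978, 1.01 and 0.995 in the order above, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test, prior count 2 for log values). The filter kept 15260 genes and removed 3092. SEs of log2 fold changes are those the F test implies. The common biological coefficient of variation was 0.0761. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The same genes were tested with DESeq2 1.42.0, whose independent filtering left 13017 without an adjusted p, and with limma 3.58.1 (voom). Introns were tested in the same way, and the share of an intron in its gene with diffSpliceDGE of edgeR and diffSplice of limma, on introns that do not overlap within a gene. R was 4.3.3. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and interval overlaps with GenomicRanges 1.54.1.

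Before the data were examined, 31 gene lists, the target gene, the comparison by longest internal exon and the alternatives not named as added were fixed. The 27 lists with at least 5 tested genes were tested against all other genes with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these, 13 passed, 8 of them up and 5 down. With a correlation estimated from the residuals 0 passed (lowest adjusted p 0.618, 0 at an unadjusted p under 0.05), and with fry, which asks whether the genes of a list move one way on balance without reference to other genes, 0 passed (lowest adjusted p 0.289). The lists of TARBP2-controlled transcripts, replication-dependent histones, mitochondrially encoded transcripts and small structured RNAs had too few tested genes. Members were also tested with the adjustment taken over the list alone, which makes no adjustment across lists. Named genes are METTL3, the 4 TARBP2-controlled transcripts, up to 12 called genes per direction with the largest log2 fold changes (at least 5 CPM in the higher group and both knockdown libraries beyond both controls), and up to 4 members of each list with the lowest p.

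The replicate numbers were not treated as pairs, since the deviations of libraries with the same number had a correlation of -0.045 across genes. A replicate term was tried as an alternative. The counts of the replicates of a group differed by a chi-square per degree of freedom of 8.79 in siControl and 2.96 in siMETTL3. Independent reads drawn from 1 library would give about 1. Reads in overlapping introns count more than once, which also raises these values. The values therefore do not settle whether the replicates of a group were prepared separately. Nothing in the labels says that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Shares of counts have Wilson 95% intervals, and these cover counting error only.

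The alternatives were DESeq2 size factors, upper quartile factors and total counts in place of TMM, no filter, at least 50 counts in 2 libraries, DESeq2, limma-voom, a test against a 1.2-fold change (glmTreat), a replicate term and each library left out in turn. A fit with a library left out keeps a lone library in that group. Its p-values and counts of calls, for genes and for lists, therefore rest on the spread within the other group alone. Added after the data were seen were sums over non-overlapping introns, sums over introns of at least 5000 nt, sums without the 8 most abundant introns, all alternatives for single introns, and the intron length results with their alternatives. Intervals of medians are 95% bootstrap intervals over genes from 2000 resamples. All tests are two-sided.

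The tests were checked on simulated counts with the libraries' depths and trended dispersion, in which 50 genes changed at each size. Of these 50, edgeR recovered 13 at 1.3-fold, 29 at 1.5-fold, 46 at 2-fold and 47 at 3-fold, with 3 false calls among 15097 genes. DESeq2 recovered 6, 18, 36 and 43, with 2 false calls, and limma-voom 13, 29, 45 and 47, with 4. For single introns edgeR recovered 1, 10, 37 and 47, with 4 false calls, and for the share of an intron in its gene 0, 1, 19 and 38, with 14 calls outside the changed introns. A list shifted by 0.3 on the log2 scale had a camera adjusted p of 1.3e-20 with the preset correlation and adjusted p = 0.192 with an estimated correlation, and 0 other lists passed. The simulated genes varied independently of each other, so this could not check the preset correlation of 0.01. In the data the correlation estimated from the residuals was 0.85 for G2/M, 0.44 for G1/S, 0.38 for ribosomal proteins and 0.048 for NF-kB. It was -0.019 for immediate early genes, below the preset 0.01, and their unadjusted camera p still went from 0.0028 to 0.080. The test with an estimated correlation missed the shifted list in the simulated counts. A list that fails it is therefore not shown to be unchanged.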

Results

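Nuclear RNA was sequenced from MDA-LM2 cells, a lung-metastatic subline of the human breast cancer line MDA-MB-231. The cells had received either a control siRNA (siControl) or an siRNA against METTL3 (siMETTL3), the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Each group held 2 libraries, numbered replicate 1 and 2, so 4 libraries were compared. The deposited values were read counts over 185763 introns of the hg19 annotation. Every gene value given here is the sum over the introns of that gene, and so is meant to follow transcripts that still carry introns. Each interval also holds 1 exon base, where reads of mature mRNA can be counted. Total counts were 12201167 in siControl 1, 13982030 in siControl 2, 11265979 in siMETTL3 1 and 13661570 in siMETTL3 2. At this depth the median SE of a gene's log2 fold change was 0.14 over the 15260 genes tested.

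A small number of introns held a large part of the counts. The 10 most abundant introns took 26.6% of the counts in siControl 1, 24.7% in siControl 2, 28.6% in siMETTL3 1 and 29.8% in siMETTL3 2. These shares count some reads more than once, since 2 of the 10 are PID1 introns that overlap and hold nearly the same reads. The control libraries lay farther apart than the knockdown libraries. The robust SD of the log2 ratio between libraries, over genes, was 0.26 for siControl 2 over siControl 1 and 0.16 for siMETTL3 2 over siMETTL3 1. For the 4 pairs of a knockdown and a control library it ran from 0.22 to 0.32, and both pairs with siControl 2 (0.29 and 0.32) exceeded both pairs with siControl 1 (0.22 and 0.23).

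The first question was what happened to the siRNA's target. METTL3 (hg19 chromosome 14, 21966513 to 21979265, 10 introns) gave 25.1 and 25.4 CPM (intron counts scaled to library size) in siControl 1 and 2 and 27.3 and 26.2 CPM in siMETTL3 1 and 2. The means were 25.3 ± 0.187 (SD, n = 2) and 26.8 ± 0.765 CPM, a log2 fold change of 0.081 (SE 0.11) with an edgeR adjusted p of 0.794. An siRNA acts mainly on spliced mRNA, which intron counts do not measure apart from unspliced RNA, so these values check neither the knockdown nor the sample labels. Other members of the m6A methyltransferase complex did not pass the test either. WTAP, the splicing-associated subunit, had a log2 fold change of -0.16 (SE 0.095), and ZC3H13, a scaffold subunit, of -0.12 (SE 0.091). Of the 7 tested genes of the complex, 0 passed the edgeR test over all genes and 0 when adjusted over the list alone, with 0 at an unadjusted p under 0.05. The median log2 fold change of the complex was 0.0036 (camera adjusted p = 0.760).

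The main comparison asked which intron-containing nuclear transcripts differed between siMETTL3 and siControl. Gene by gene, 1 transcript rose and 6 fell among the 15260 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0476 for each). F13A1, which encodes the A chain of coagulation factor XIII, rose from 19.1 ± 1.42 to 31.4 ± 1.67 CPM (SD, n = 2 per group), a log2 fold change of 0.72 (SE 0.11). TPST2, a sulfotransferase of the Golgi, went from 36.8 ± 4.79 to 22.2 ± 0.535 CPM (log2 fold change -0.73, SE 0.12). GALNT14, an enzyme that starts O-linked glycosylation, went from 46.0 ± 3.40 to 27.9 ± 1.37 CPM (log2 fold change -0.72, SE 0.11). FRMD6-AS2, an antisense transcript of the FERM-domain gene FRMD6, went from 345 ± 22.9 to 212 ± 6.02 CPM (log2 fold change -0.70, SE 0.10).

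The other 3 genes that fell encode membrane proteins or their subunits. KCNQ3, a voltage-gated potassium channel subunit, went from 119 ± 2.18 to 77.9 ± 0.454 CPM, with a log2 fold change of -0.60 (SE 0.091). BACE2, an aspartyl protease that can cleave APP, went from 134 ± 5.55 to 89.3 ± 2.46 CPM, with a log2 fold change of -0.58 (SE 0.092). CACNB4, a calcium channel beta subunit, went from 119 ± 0.206 to 80.8 ± 0.147 CPM, with a log2 fold change of -0.56 (SE 0.090). In all 7 genes both knockdown libraries lay beyond both control libraries. On hg19 the introns of F13A1 span 6146005 to 6320819 of chromosome 6 and those of TPST2 26922233 to 26986016 of chromosome 22. Those of GALNT14 span 31133925 to 31360823 of chromosome 2, and those of CACNB4 152695893 to 152955462 of the same chromosome. The FRMD6-AS2 introns span 51921533 to 52066544 of chromosome 14 and overlap FRMD6, from which the counts, taken without regard to strand, cannot separate them. KCNQ3 lies at 133142243 to 133459447 of chromosome 8 and BACE2 at 42540502 to 42647297 of chromosome 21.

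Far more genes stood apart at the unadjusted level than passed the correction. At an unadjusted p under 0.05 edgeR counted 1998 genes (995 higher and 1003 lower in siMETTL3), against 763 that chance would give. In 6808 genes, or 44.6%, both knockdown libraries lay on the same side of both control libraries, against 33.3% expected on average. Genes of some lists move together, with an estimated correlation of 0.85 in the G2/M list, the highest of the lists tested, and 0.0098 in the ZNF list. Both counts can therefore lie far from their expectation without an effect of the siRNA. DESeq2 left 13017 of the genes without an adjusted p and called 4 up and 64 down, including 4 of the 7 edgeR genes. Limma-voom called 0, and the unadjusted p was under 0.05 in 896 genes with DESeq2 and in 1994 with limma-voom. Upper quartile factors and a filter of at least 50 counts in 2 libraries gave 0 edgeR calls, and a replicate term 89 up and 97 down. A fit with a library left out keeps a lone library in that group, so its calls rest on the spread within the other group. Without siControl 1 edgeR called 1009 genes up and 1983 down, and without siControl 2 it called 394 up and 555 down, each including all 7 genes. Without siMETTL3 1 it called 1 up and 3 down, including 1 of the 7 (F13A1), and without siMETTL3 2 it called 0.

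**Figure D1:**
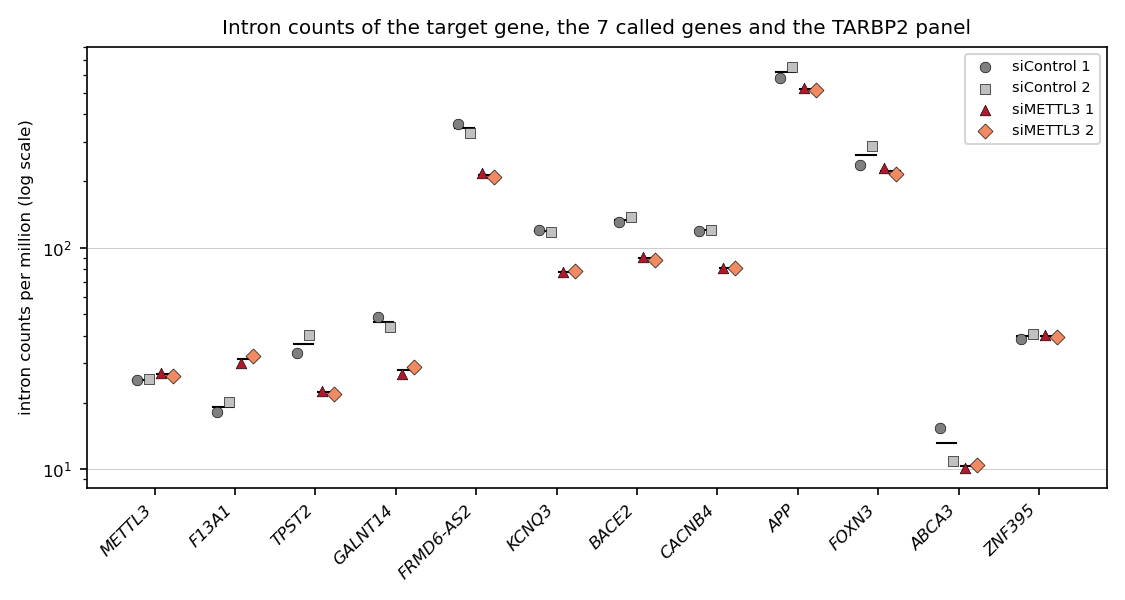
Intron CPM of METTL3, the 7 called genes and the 4 TARBP2-controlled transcripts on a log axis, with points for libraries and bars for group means. F13A1 is higher in both siMETTL3 libraries (mean 31.4 CPM) than in both siControl libraries (mean 19.1 CPM), and METTL3 lies between 25.1 and 27.3 CPM in all 4.

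A panel of 4 transcripts reported to be controlled by TARBP2, a double-stranded RNA-binding protein, was fixed beforehand. None of the 4 passed the edgeR test, over all genes or adjusted over the list alone, while 2 had an unadjusted p under 0.05. APP, the amyloid precursor protein gene, went from 617 to 519 CPM (log2 fold change -0.25, SE 0.11, n = 2 per group, edgeR adjusted p = 0.335, and 0.0919 over the list alone). FOXN3, a forkhead repressor, went from 262 to 222 CPM (log2 fold change -0.24, SE 0.11, edgeR adjusted p = 0.372, and 0.0919 over the list alone). Its introns overlap those of FOXN3-AS1, from which counts taken without regard to strand cannot separate them. ABCA3, a lipid transporter, had 13.1 and 10.3 CPM (log2 fold change -0.34, SE 0.17, edgeR adjusted p = 0.420, and 0.0942 over the list alone). ZNF395, a zinc finger transcription factor, had 39.8 CPM in both groups. In APP, FOXN3 and ABCA3 both knockdown libraries lay below both controls. Without siControl 1 the log2 fold changes were -0.34 for APP, -0.39 for FOXN3 and -0.084 for ABCA3. Without siControl 2 they were -0.17 for APP, -0.092 for FOXN3 and -0.57 for ABCA3. Each of these fits has a lone control library, so it cannot measure the spread between controls.

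Cell-cycle genes were higher in siMETTL3. Of 50 G2/M and mitosis genes 49 had higher intron counts in siMETTL3, with a median log2 fold change of 0.39 (quartiles 0.32 and 0.47). The list rose against all other genes (camera adjusted p = 1.4e-17), with adjusted p = 0.62 with an estimated correlation. In simulated counts that setting missed a list shifted by 0.3 (camera adjusted p = 0.192). Here and below it therefore cannot decide whether a list changed. In the edgeR test 0 genes of the G2/M list passed over all genes, with 41 at an unadjusted p under 0.05, whereas 40 rose and 0 fell when adjusted over the list alone. CKAP2, a spindle-associated protein, had a log2 fold change of 0.57 (SE 0.11, 28.3 to 41.9 CPM) and AURKA, the mitotic kinase Aurora A, of 0.55 (SE 0.11, 69.8 to 102 CPM). CCNB2, a mitotic cyclin, had 0.56 (SE 0.12) and MKI67, the proliferation marker Ki-67, 0.49 (SE 0.11), each with an edgeR adjusted p of 0.0037 over the list alone. In 44 of the 50 genes both knockdown libraries lay above both controls.

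The G1/S and DNA replication list moved the same way. Of its 43 genes 42 were higher, with a median log2 fold change of 0.30, and the list rose against all other genes (camera adjusted p = 4.0e-11), with adjusted p = 0.62 with an estimated correlation. In the edgeR test 0 passed over all genes, with 24 at an unadjusted p under 0.05, and 7 rose when adjusted over the list alone. MCM4, a subunit of the replicative helicase, had a log2 fold change of 0.56 (SE 0.11, 20.8 to 30.7 CPM), and E2F1, a transcription factor of S-phase entry, 0.77 (SE 0.20, 7.85 to 13.2 CPM). CDC6, a replication licensing factor, had 0.37 (SE 0.11) and HELLS, a chromatin remodeler, 0.32 (SE 0.093).

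The control libraries differed from each other in both cell-cycle lists. The median log2 ratio of siControl 2 over siControl 1 was -0.27 for G2/M and -0.20 for G1/S, against -0.019 and -0.058 between the knockdown libraries. The medians of the 4 knockdown over control pairs ran from 0.26 to 0.54 for G2/M and from 0.18 to 0.40 for G1/S. Without siControl 2, with a lone control library left, the median difference in log2 CPM was 0.25 for G2/M and 0.21 for G1/S. With all libraries each list had adjusted p = 0.62 with an estimated correlation.

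**Figure D2:**
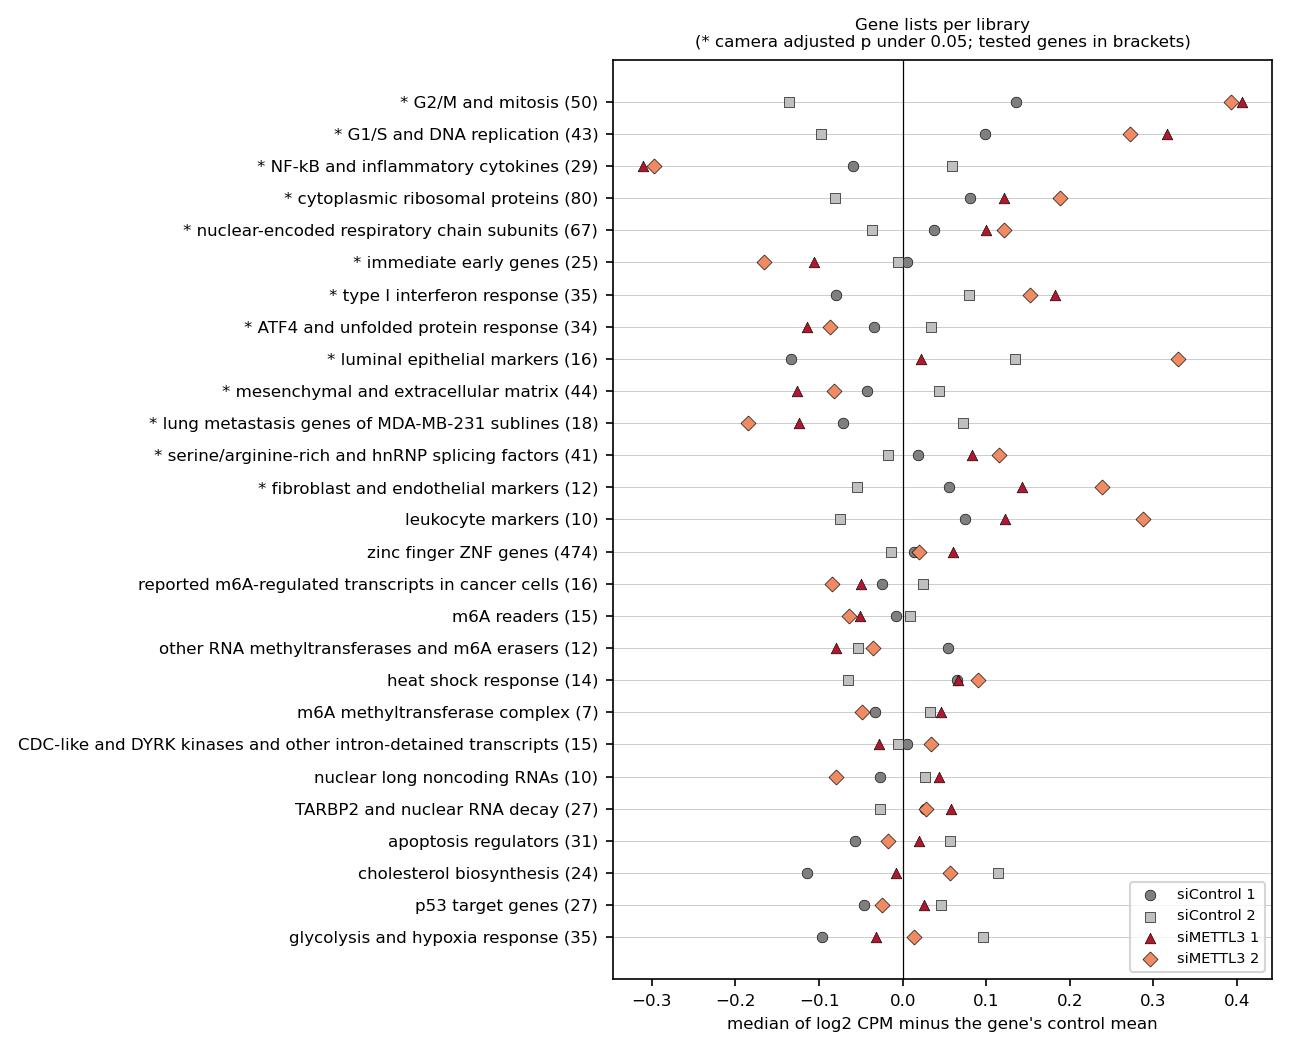
Median log2 CPM of each gene list per library, relative to the control mean of each gene, with an asterisk where the camera adjusted p was under 0.05. For the G2/M list both siMETTL3 points lie above both siControl points, while the control points are themselves 0.27 apart.

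Inflammatory genes moved the other way. Of 29 NF-kB and inflammatory cytokine genes 27 were lower in siMETTL3, with a median log2 fold change of -0.36. The list fell against all other genes (camera adjusted p = 6.2e-07), with adjusted p = 0.62 with an estimated correlation. In the edgeR test 8 genes fell when adjusted over the list alone and 0 over all genes, with 11 at an unadjusted p under 0.05. SOD2, the mitochondrial superoxide dismutase, had a log2 fold change of -0.50 (SE 0.098, 55.9 to 39.4 CPM), and PTGS2, the inducible cyclooxygenase, -0.60 (SE 0.14, 20.7 to 13.6 CPM). The cytokine genes IL6 (-0.61, SE 0.15, 20.2 to 13.1 CPM) and CSF2 (-1.32, SE 0.37, 2.51 to 0.996 CPM) also fell over the list alone. The median log2 ratio of siControl 2 over siControl 1 was 0.12 in this list. The median difference in log2 CPM without siControl 2, with a lone control library left, was -0.20.

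Smaller falls were found in lists of signaling, stress and invasion. Immediate early genes, which respond first to growth factors, had 17 of 25 lower, with a median log2 fold change of -0.11 (camera adjusted p = 0.0128, and adjusted p = 0.62 with an estimated correlation). MYC had a log2 fold change of -0.58 (SE 0.18, 9.77 to 6.57 CPM) and the phosphatase gene DUSP5 -0.29 (SE 0.092), neither past the edgeR test over this list alone, where 0 passed and 5 had an unadjusted p under 0.05. The ATF4 and unfolded protein response list had 25 of 34 lower, with a median of -0.096 (camera adjusted p = 0.0173, and adjusted p = 0.62 with an estimated correlation). The only member past the test over that list alone went the other way. It was PHGDH, which starts serine synthesis, with 0.66 (SE 0.17, 10.4 to 16.4 CPM). The median log2 ratio of siControl 2 over siControl 1 was -0.010 for the immediate early and 0.068 for the ATF4 list. Without siControl 2 the ATF4 list had a camera adjusted p of 0.27. The immediate early list had 0.11 without siControl 1 and 0.059 without siMETTL3 2, and its median difference in log2 CPM, -0.11 with all libraries, was -0.16 without siControl 2 and -0.17 without siMETTL3 1.

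Mesenchymal and extracellular matrix genes had 30 of 44 lower, with a median log2 fold change of -0.10 (camera adjusted p = 0.0274, and adjusted p = 0.62 with an estimated correlation). Over the list alone 2 fell, among them ZEB2, a repressor of epithelial genes (-0.40, SE 0.095, 79.9 to 60.5 CPM). Of 18 genes linked to lung metastasis of MDA-MB-231 sublines 14 were lower, with a median of -0.14 (camera adjusted p = 0.0290, and adjusted p = 0.62 with an estimated correlation). In that list PTGS2 fell and ALDH3A1, an aldehyde dehydrogenase, rose over the list alone (1.51, SE 0.34, 0.996 to 2.88 CPM). In the edgeR test over all genes 0 genes of either list passed, with 11 and 5 at an unadjusted p under 0.05. In siControl 2 over siControl 1 the median log2 ratio was 0.086 for the mesenchymal list and 0.14 for the metastasis list. Left out in turn, siControl 2 (camera adjusted p = 0.13) and siMETTL3 1 (0.13) ended the mesenchymal call, whose median difference in log2 CPM was -0.13 without siMETTL3 2 and -0.078 with all libraries, and siControl 2 (0.32) and siMETTL3 2 (0.20) the metastasis call.

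Genes of the translation and respiration machinery were higher. Of 80 cytoplasmic ribosomal protein genes 65 were higher, with a median log2 fold change of 0.17 (camera adjusted p = 1.2e-05, and adjusted p = 0.62 with an estimated correlation). Over the list alone 4 rose, RPLP0 (0.43, SE 0.11), RPS2 (0.54, SE 0.14), RPLP2 (0.44, SE 0.12) and RPL19 (0.39, SE 0.10), and over all genes 0 in the edgeR test, with 20 at an unadjusted p under 0.05. Nuclear-encoded respiratory chain subunits had 55 of 67 higher, with a median of 0.11 (camera adjusted p = 0.0069, and adjusted p = 0.62 with an estimated correlation) and 0 members past the edgeR test over the list alone, while 1 had an unadjusted p under 0.05. Splicing factors of the serine/arginine-rich and hnRNP classes had 30 of 41 higher, with a median of 0.10 (camera adjusted p = 0.0447, and adjusted p = 0.62 with an estimated correlation). HNRNPH3 (0.26, SE 0.090) and PTBP1 (0.25, SE 0.099) were among its 4 genes with the lowest p, but 0 passed the edgeR test over the list alone, with 7 at an unadjusted p under 0.05. The median log2 ratio of siControl 2 over siControl 1 was -0.16, -0.074 and -0.036 in these 3 lists. Without siControl 2 their median differences in log2 CPM were 0.081, 0.087 and 0.061 with a camera adjusted p of 0.11, 0.13 and 0.19. The splicing factor call was also lost without siControl 1 (0.066), without siMETTL3 1 (0.24), without siMETTL3 2 (0.21) and with a replicate term (0.13).

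The type I interferon response list had 28 of 35 genes higher, with a median log2 fold change of 0.14 (camera adjusted p = 0.0162, and adjusted p = 0.62 with an estimated correlation). IFIT1 had a log2 fold change of 0.69 (SE 0.21, 6.90 to 11.1 CPM) and XAF1 0.49 (SE 0.15, 9.58 to 13.5 CPM), neither past the edgeR test over the list alone (adjusted p = 0.103 for both), and 2 genes had an unadjusted p under 0.05. Here the median log2 ratio of siControl 2 over siControl 1 was 0.16. Without siControl 1 the median difference in log2 CPM was 0.027 (camera adjusted p = 0.34), and without siMETTL3 1 the camera adjusted p was 0.086.

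Markers of other cell types were mostly higher in siMETTL3. Luminal epithelial markers had 14 of 16 higher with a median log2 fold change of 0.21 (camera adjusted p = 0.0274, and adjusted p = 0.62 with an estimated correlation). Fibroblast and endothelial markers had 10 of 12 higher with a median of 0.15 (camera adjusted p = 0.0447, and adjusted p = 0.62 with an estimated correlation). Leukocyte markers had 8 of 10 higher with a median of 0.14, not past the test (camera adjusted p = 0.192). GATA3, a luminal transcription factor, had 3.31 and 5.62 CPM (0.75, SE 0.26), PDGFRA, a receptor of fibroblasts, 1.66 and 3.05 CPM (0.87, SE 0.30), and PTPRC, the leukocyte antigen CD45, 21.6 and 26.7 CPM (0.31, SE 0.12), none past the edgeR test over its list alone. In siControl 2 over siControl 1 the median log2 ratio was 0.27 for the luminal, -0.11 for the fibroblast and endothelial and -0.15 for the leukocyte list. Left out in turn, siControl 1 (camera adjusted p = 0.41) and siMETTL3 2 (0.33) ended the luminal call, whose median difference in log2 CPM was 0.11 without siControl 1, 0.022 without siMETTL3 2, 0.32 without siMETTL3 1 and 0.19 with all libraries, and siControl 1 (0.051), siControl 2 (0.32) and siMETTL3 2 (0.17) the fibroblast and endothelial call. The median difference in log2 CPM of that list, 0.15 with all libraries, was 0.24 without siControl 1, 0.065 without siControl 2 and 0.23 without siMETTL3 1. The leukocyte list passed camera without siMETTL3 1 at the preset correlation (0.28, camera adjusted p = 0.024). With all libraries it had adjusted p = 0.62 with an estimated correlation.

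Lists built around m6A itself did not pass the set test. In the edgeR test over all genes 0 of their members passed, and calls over a list alone are not adjusted across lists. The 15 tested m6A readers had a median log2 fold change of -0.048 (camera adjusted p = 0.404). IGF2BP2, a reader that stabilizes bound mRNA, was the only reader to fall over the list alone (-0.48, SE 0.10, 507 to 363 CPM, edgeR adjusted p = 0.0054). The 12 other RNA methyltransferases and m6A erasers had a median of -0.038 (camera adjusted p = 0.611), with the eraser FTO at -0.19 (SE 0.11). Of 16 transcripts reported as m6A-regulated in cancer cells, 1 rose and 2 fell over the list alone, and the median was -0.080 (camera adjusted p = 0.404). FOXM1, a transcription factor of mitotic genes, rose (0.50, SE 0.12, 34.3 to 48.3 CPM), while BCL2, an inhibitor of apoptosis (-0.37, SE 0.11, 40.2 to 31.3 CPM), and MYC fell. With a library left out the median difference in log2 CPM of that list ran from -0.092 to 0.010, positive without siControl 1 (0.0030) and without siControl 2. In the same fits that of the other methyltransferases and erasers ran from -0.080 to 0.047, against -0.042 with all libraries. For the readers it ran from -0.11 to -0.051, against -0.048 with all libraries. For the m6A complex it ran from -0.087 to 0.089, against 0.0078 with all libraries.

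The remaining lists gave no set call, and 0 of their members passed the edgeR test over all genes. Among glycolysis and hypoxia genes (35 tested, camera adjusted p = 0.898) 2 rose and 3 fell over the list alone. The lower enzymes GAPDH (0.44, SE 0.099, 42.1 to 57.0 CPM) and LDHA (0.36, SE 0.095, 163 to 208 CPM) rose, and the hexokinases HK2 (-0.41, SE 0.10, 53.3 to 40.3 CPM) and HK1 (-0.33, SE 0.096, 182 to 145 CPM) fell. PVT1, the long noncoding RNA beside MYC, fell over the list of 10 nuclear long noncoding RNAs (-0.41, SE 0.11, 500 to 377 CPM), whose median was 0.00094 (camera adjusted p = 0.768). DDB2, a DNA damage sensor, rose over the list of 27 p53 targets (0.51, SE 0.12, 20.6 to 29.3 CPM), whose median was -0.0090 (camera adjusted p = 0.898). The other 6 lists had 0 members past the edgeR test over the list alone. The heat shock response (14 tested) had a median log2 fold change of 0.074 and a camera adjusted p of 0.611, with 3 genes at an unadjusted p under 0.05. The CDC-like and DYRK kinases with other intron-detained transcripts (15 tested) had a median of 0.0045 (camera adjusted p = 0.768, 0 genes at that level), and TARBP2 with nuclear RNA decay factors (27 tested) a median of -0.0031 (camera adjusted p = 0.841, 3 genes). Apoptosis regulators (31 tested) had a median of 0.029 (camera adjusted p = 0.865, 3 genes), cholesterol biosynthesis (24 tested) 0.0045 (camera adjusted p = 0.870, 2 genes) and 474 zinc finger ZNF genes 0.033 (camera adjusted p = 0.338, 31 genes). With a library left out the median turned sign in 10 of the 14 lists without a set call, all but the leukocyte, ZNF, reader and heat shock lists. The median, the mean and the test differed in sign in 8 lists, 0 of them past the set test. They were the m6A complex, the CDC-like and DYRK kinases, nuclear long noncoding RNAs, TARBP2 and RNA decay, apoptosis, cholesterol, p53 targets and glycolysis.

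Over introns of at least 5000 nt, a setting added after the values were seen, 6 of the 13 lists still passed camera at the preset correlation. With all introns each of the 13 had adjusted p = 0.62 with an estimated correlation. The median difference in log2 CPM lay near 0 in the ribosomal protein list, with 8 genes left (0.0088 from 0.17, camera adjusted p = 0.87), in splicing factors (0.011 from 0.099, 0.95) and in immediate early genes (-0.0035 from -0.11, 0.73). The call also ended in 4 lists whose median changed less, namely the ATF4 list (-0.090 from -0.091, camera adjusted p = 0.11), respiratory chain subunits (0.089 from 0.11, 0.18), luminal markers (0.15 from 0.19, 0.22) and lung metastasis genes (-0.10 from -0.15, 0.13). The G2/M (4.2e-12), G1/S (1.3e-07), NF-kB (0.0053), interferon (0.00047), mesenchymal (0.041) and fibroblast and endothelial (0.0050) lists kept a camera adjusted p under 0.05, and the median of the interferon list was 0.24 and that of the fibroblast and endothelial list 0.40.

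**Figure D3:**
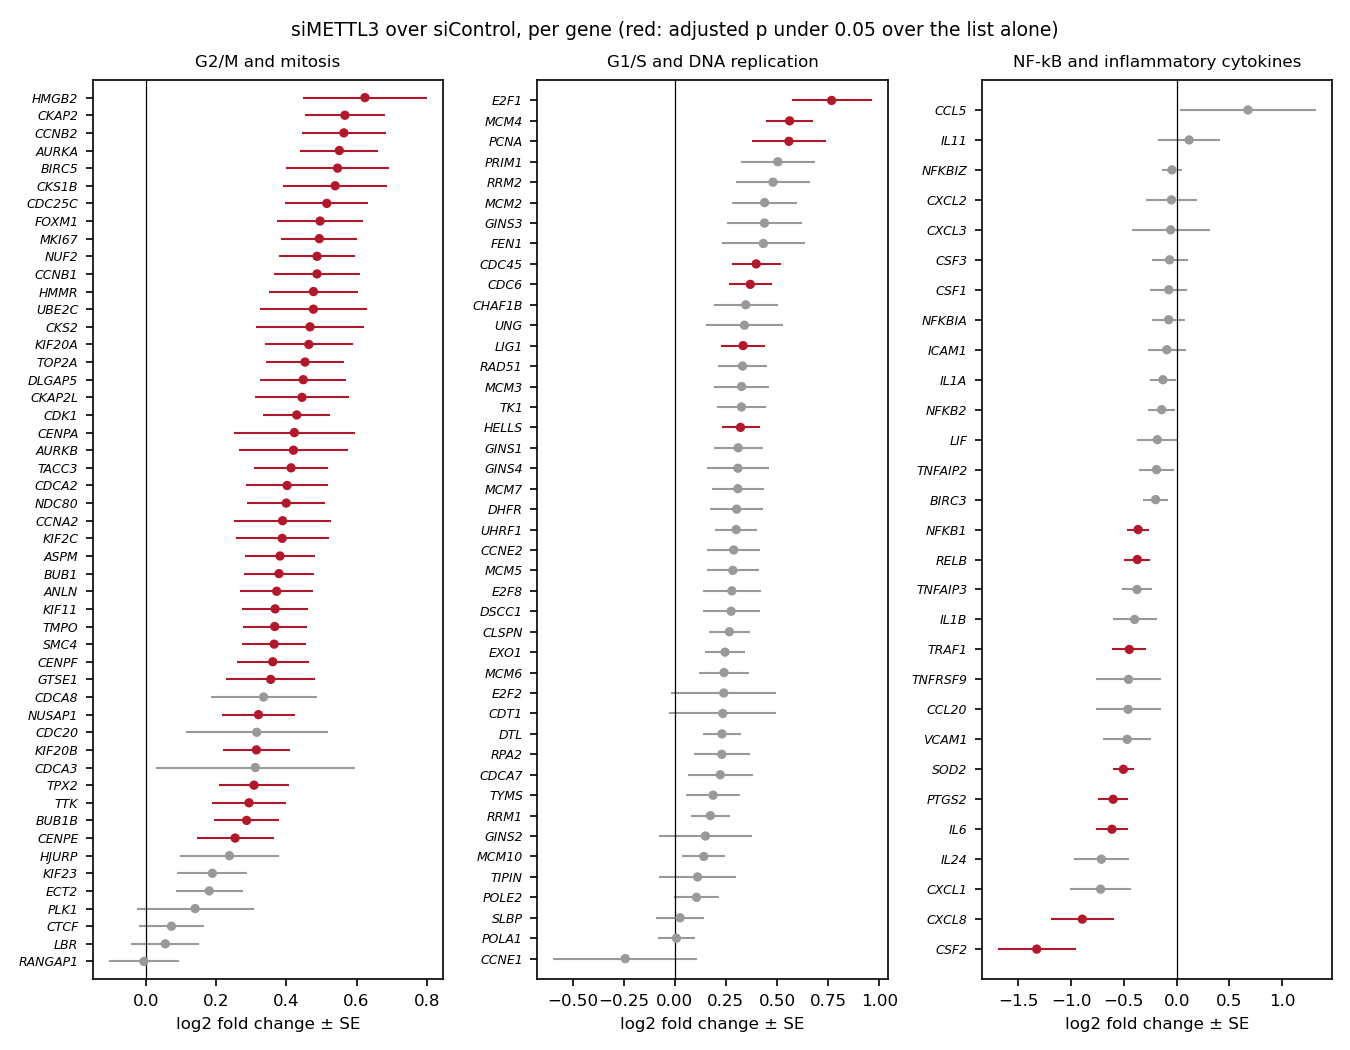
Log2 fold change of the tested genes of the G2/M, G1/S and NF-kB lists, with points for genes, bars for 1 SE, and red for an edgeR adjusted p under 0.05 over the list alone. G2/M genes such as AURKA (0.55) lie to the right of 0 and NF-kB genes such as SOD2 (-0.50) to the left.

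A further question was whether single introns changed apart from their genes. Of 93913 introns tested, 5 rose and 28 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 8236 at an unadjusted p under 0.05. The introns named here were chosen after their values were seen. The rising introns lay in SLCO4A1, an organic anion transporter gene, in its antisense transcript SLCO4A1-AS1, in SPA17 and in STMN1, a microtubule regulator gene. The SLCO4A1 intron at 61300430 to 61303101 of chromosome 20 had a log2 fold change of 0.92 (SE 0.16, adjusted p = 0.0269), and the SLCO4A1-AS1 intron lies inside the other SLCO4A1 intron, so the reads of the inner intron are also counted in the outer. The largest fall was in an intron of RCAN1, a calcineurin inhibitor gene, at 35896008 to 35898960 of chromosome 21. Its counts were 59 and 88 in siControl 1 and 2 and 15 and 29 in siMETTL3 1 and 2 (log2 fold change -1.66, SE 0.26, adjusted p = 0.0101). The 28 falling introns lay in 20 genes and formed 21 separate stretches, and 27 of them were at least 5000 nt long. HDAC9, a histone deacetylase gene, held 4 of them, FYN, a Src-family kinase gene, 1 (-0.65, SE 0.13), and SOD2 1 (-0.74, SE 0.15). Of the genes holding falling introns 6 also fell as genes, and of those holding rising introns 0. Without siControl 1 the counts were 993 rising and 2861 falling, without siControl 2 190 and 535, without siMETTL3 1 0 and 0, and without siMETTL3 2 0 and 1.

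No change in the share that an intron takes of the counts of its gene was called. In 85047 introns of 11342 genes edgeR (diffSpliceDGE) called 0, with 2570 at an unadjusted p under 0.05, and limma (diffSplice) called 0, with 3270.

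Intron length was examined after the values were seen. The 1965 introns of at most 200 nt had a median log2 fold change of 0.18, with 68.1% above 0. The 36685 introns of at least 5000 nt had a median of -0.024, with 46.1% above 0. In introns of 1 to 100 nt the medians of the 4 knockdown over control pairs ran from 0.11 to 0.24. There siMETTL3 2 over siMETTL3 1 gave 0.059, and siControl 2 over siControl 1 gave -0.047. In the next class, up to 200 nt, the same control pair gave -0.098. The edgeR test called 0 of the 1965 short introns, and in simulated counts it recovered 1 of 50 introns changed 1.3-fold, so single introns with such a shift were not detectable at this depth. Without siControl 1 the median over introns of at most 200 nt was 0.27.

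**Figure D4:**
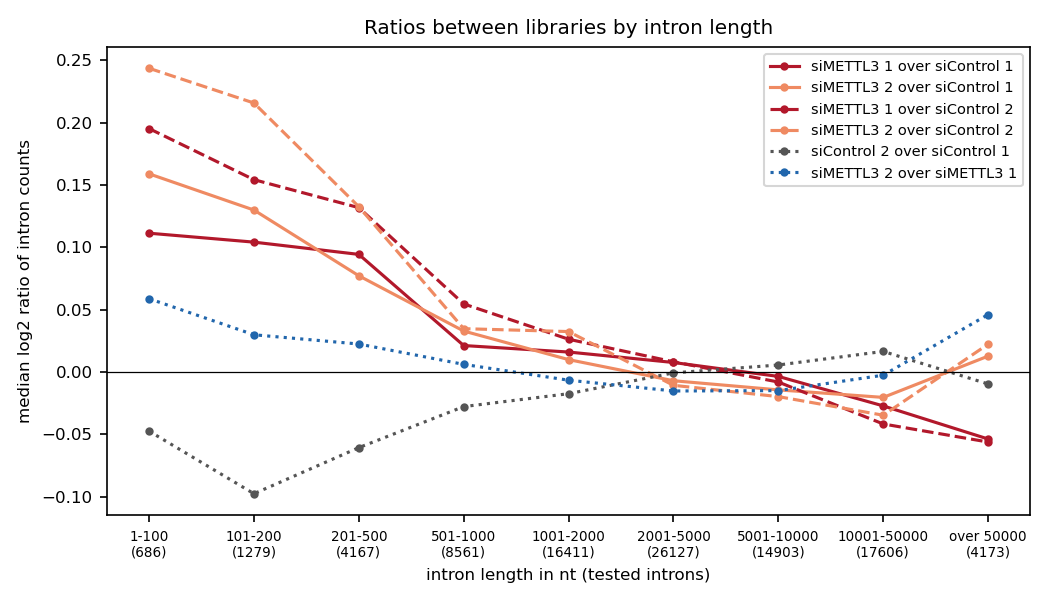
Median log2 ratio of intron counts by intron length, with a line for each of the 4 knockdown over control pairs and dotted lines for the pairs within a group. In the class of 1 to 100 nt the 4 pairs lie between 0.11 and 0.24, the control pair lies at -0.047 and the knockdown pair at 0.059.

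The last comparison asked whether genes with a long internal exon, where m6A is frequent, differed from the rest. Overlapping exons were merged over all transcripts of a gene in the GENCODE v29 basic annotation, and the first and last merged exons were left out. A merged internal exon can therefore join exons of several transcripts or hold an alternative first or last exon. Of 14616 genes with at least 3 merged exons, 6105 had a merged internal exon over 400 nt. Their median log2 fold change was 0.0013, and that of the other 8511 was 0.016. The difference of -0.014 was smaller in size than that between the control libraries, 0.023, and ran from -0.037 to 0.0039 over the 4 pairs. Without siControl 1 it was -0.033, and without siControl 2 -0.00037.

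Shares of all counts were small for the RNA classes fixed beforehand. Introns of ribosomal protein genes held 0.236% of counts in siControl 1 (Wilson 95% interval 0.233 to 0.238), 0.203% in siControl 2 (0.201 to 0.206), 0.240% in siMETTL3 1 (0.237 to 0.243) and 0.243% in siMETTL3 2 (0.240 to 0.245). Nuclear long noncoding RNA introns held 0.151% (0.149 to 0.153), 0.160% (0.158 to 0.162), 0.140% (0.138 to 0.143) and 0.138% (0.136 to 0.140) in the same order. The 4 introns of replication-dependent histone genes held 0.00191% (0.00168 to 0.00217), 0.00200% (0.00177 to 0.00224), 0.00188% (0.00164 to 0.00215) and 0.00185% (0.00164 to 0.00209). With 2 libraries against 2, a two-sided exact permutation test of a share cannot give a p below 0.333.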

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

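Tests of introns of at least 5000 nt, of non-overlapping introns, without the 8 most abundant introns, of single introns and of short introns were chosen after the result was seen. The numbers of genes called moved with most settings, while the direction of all 7 called genes was the same in every alternative. Genes rising after METTL3 knockdown (1 as reported) numbered 2 with DESeq2 size factors, 0 with upper quartile factors, 3 with total counts only, 8 with no filter, 0 with at least 50 counts, 89 with a replicate block, 4 with DESeq2, 0 with limma-voom (1994 genes at an unadjusted p under 0.05), 0 with glmTreat and 0 over introns of at least 5000 nt. Genes falling (6 as reported) numbered 10, 0, 13, 19, 0, 97, 64, 0, 0 and 0 under the same settings. With a library left out they ranged from 0 to 1009 rising and from 0 to 1983 falling, the lone library being assumed to vary like the other group. All 7 genes were among those called with DESeq2 size factors, total counts, no filter, the replicate block, without siControl 1, without siControl 2 and without the 8 most abundant introns. The cause of these changes was not tested.

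Introns rising (5 as reported) numbered 30 with no filter, 0 with at least 50 counts and 23 with a replicate block, and falling introns (28) 211, 1 and 46. They ranged from 0 to 993 rising and from 0 to 2861 falling with a library left out. Gene lists past the set test (13) numbered 0 with an estimated correlation, 0 with fry, 6 over introns of at least 5000 nt, and from 6 (without siControl 2) to 11 with a library left out, and each of the 13 kept its sign. The difference by longest internal exon ranged from -0.033 (without siControl 1) to -0.00037, and the median of introns of at most 200 nt from 0.14 to 0.27. The METTL3 value, from 0.045 to 0.11, passed in no setting, and DESeq2 gave it no adjusted p. Over 114 named genes 1466 values kept direction and, where an adjusted p was given, side of the threshold. Of the others 136 newly passed, 43 no longer passed and 6 turned. ZNF395 (-0.00031) was 0.013 with upper quartile factors, 0.0061 with total counts, 0.0090 with at least 50 counts and -0.048 to 0.037 with a library left out, and CASP2 (0.26) was -0.078 over introns of at least 5000 nt. The cause was not tested. Scaling moved the median over all genes by little, to 0.024 with upper quartile factors from 0.011. Single introns held few counts, with a median of 9 in both controls, 8 in siMETTL3 1 and 10 in siMETTL3 2.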

Other observations

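The tests of gene families, of read density in short and long introns, of evenly spread background and of other cell types were chosen only after the result was seen. Among 188 gene families defined by a shared symbol stem with at least 10 tested members, 3 passed the camera test, all with higher intron counts in siMETTL3 (adjusted p = 0.0454 each, and adjusted p = 0.923 with an estimated correlation). The RPL stem of large-subunit ribosomal proteins had 44 of 56 genes higher, with a median log2 fold change of 0.13, and the MCM stem, which holds the replicative helicase, 9 of 10 with a median of 0.26. Stems were not tested over introns of at least 5000 nt. The PCDH stem of protocadherins, which are cell adhesion molecules, had 11 of 12 higher with a median of 0.23, among them PCDH12 (0.55, SE 0.23), PCDH9 (0.25, SE 0.11) and PCDH15 (0.25, SE 0.11). The DOCK stem of guanine nucleotide exchange factors had 9 of 10 lower with a median of -0.17, short of the test (camera adjusted p = 0.202), and the KRT stem of keratins 13 of 14 higher with a median of 0.16 (camera adjusted p = 0.191). None of the named PCDH genes passed the edgeR test over all genes. The stem also counts PCDH9-AS3, whose introns lie inside an intron of PCDH9, so that counts taken without regard to strand cannot separate them and no value is given for it.

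The most abundant introns were few and lay in genes not tied to breast cells. An intron of UNC45B, a myosin chaperone of muscle, at 33477242 to 33479911 of hg19 chromosome 17 held 8.43% of all counts in siControl 1, 7.57% in siControl 2, 9.37% in siMETTL3 1 and 9.57% in siMETTL3 2. An intron of ANKRD30BL held 4.89%, 4.88%, 5.65% and 5.27%, and an intron of HFM1 3.51%, 3.40%, 3.80% and 3.92%. These introns were chosen after their values were seen.

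The first pattern weighed is the higher intron counts of the G2/M and G1/S lists. If spliced mRNA read at the exon base of each interval carried it, long introns would show at most a median of 0.19, but over introns of at least 5000 nt the G2/M median was 0.38 (95% interval 0.30 to 0.41, 32 genes), which argues against that. The values met the prediction set for a control library standing apart, since the lowest of the 4 pair medians, 0.26, did not exceed the 0.27 between the control libraries. The knockdown libraries lay above siControl 1 (0.27 and 0.26) as well as above siControl 2 (0.53 and 0.54). A rise thus remained against either control, but the rise over siControl 1 was about as large as the spread between the controls. Without siControl 2 the median difference in log2 CPM was 0.25, and without siControl 1 it was 0.52. Each rests on a lone control library, and the 0.25 is no larger than the 0.27 between the controls. With all libraries the G2/M list had adjusted p = 0.62 with an estimated correlation. A difference in cycling between the cultures and an effect of METTL3 remain open and were not tested.

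The second pattern is the higher counts of short introns. A different set of genes holding the short introns is argued against by a median within-gene difference of 0.11 (95% interval 0.092 to 0.127) between introns of at most 500 nt and of at least 5000 nt, higher in 1414 of 2202 genes. Reads of spliced mRNA could add more to short introns, and the within-gene difference was larger by 0.024 in genes with a high than in genes with a low short-to-long read density (95% interval -0.019 to 0.070). That interval spans 0, so spliced mRNA cannot be told apart from a change in intron-containing RNA, and an effect of METTL3 on splicing was not tested.

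The third pattern is the higher marker lists of other cell types, and evenly spread background such as genomic DNA, which would raise the lowest 2524 genes, cannot be told apart from a change in the cells. The median rise of those genes ran from -0.0018 to 0.0078 CPM per kb over the 4 pairs, against -0.0036 and 0.0058 within the groups, and the pooled ratio of knockdown to control was 1.07, 1.09, 1.10 and 1.03 in the lowest 4 of 10 classes of genes by read density, from 0.927 to 0.938 in classes 5 to 9 and 1.05 in the densest. Cells of another type could raise markers of 1 type alone, and the 3 medians (0.21, 0.14 and 0.15) differed by 0.063 with an upper limit of 0.40, so this source cannot be told apart from a change in the cells themselves. Among the most abundant markers were KRT8 (111 and 119 CPM) of the luminal list, LCP1 (26.3 and 28.7) and PTPRC (21.6 and 26.7) of the leukocyte list, and EMCN (20.9 and 22.6) and COL1A1 (12.3 and 12.3) of the fibroblast and endothelial list. Of the tested markers 10 of 16, 5 of 10 and 5 of 12 reach 5 CPM here, and 2, 0 and 4 are in another fixed list.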
